A study of Mus musculus with 9 samples.

How the data were processed

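Total RNA from the colon of C57BL/6J mice was sequenced on an Illumina instrument after Trizol extraction, per the labels' protocols. The 9 libraries fall into 3 groups of 3: Control, DSS and DSS with GsMTx4 (the GsMTx4 group). Groups and replicate numbers were taken from the sample titles. The labels do not state that the libraries of a group came from separate mice, so the p-values measure the spread between these samples.

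The authors deposited 1 table of FPKM values (fragments scaled to transcript length and to the number of mapped fragments) for 35315 genes in the 9 libraries. Reads were trimmed with cutadapt and inspected with FastQC, and the genome build was GRCm38, per the submitters' processing notes. The aligner and the program that computed the FPKM values are not given in the sources used here. FPKM is already divided by gene length and library size, so the values are not counts and the depth of each library is unknown. Of the 35315 genes, 35196 had a symbol and a position in the GENCODE M21 annotation of GRCm38, and 119 had no symbol. There were 53 symbols on more than 1 gene, and these were kept apart by gene identifier.

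The values were transformed to log2(FPKM + 1). Fold changes are on that scale, which understates the change of genes with low values. Genes with an FPKM of at least 1 in at least 3 of the 9 libraries were tested, whatever their group, which left 14360 genes. limma 3.58.1 in R 4.3.3 fitted all 9 libraries together with 1 mean per group (6 residual degrees of freedom), with the empirical Bayes step following the trend of spread with expression. Tests were two-sided. P-values were adjusted by the Benjamini-Hochberg method over all tested genes of a comparison, and a gene passed at an adjusted p under 0.05 with no minimum fold. The comparisons were: DSS against Control, GsMTx4 against DSS, and GsMTx4 against Control.

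Gene lists for immune, epithelial, stromal and contaminating cell types and for pathways were written down with the tests, the alternatives and the rule for named genes before the data were examined. Each list with at least 3 tested members was tested with camera from limma, with a preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over the lists of a comparison. camera was run again with a correlation estimated for each list, and fry was run as a test of the list by itself. Members were also adjusted over the list alone. The named genes are the 6 largest rises and 6 largest falls among passing genes whose groups did not overlap (3 and 3 for GsMTx4 against Control), leaving out predicted genes and immunoglobulin and T cell receptor segments. In addition, the rule takes from each list the 2 members with the smallest p, every passing member where at most 5 passed, and the 6 largest changes among genes that moved in opposite directions in DSS against Control and GsMTx4 against DSS. Piezo1, Piezo2, Il1b, Il6 and Tnf are given whatever their p.

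DSS against Control and GsMTx4 against DSS share the DSS libraries with opposite sign, so their fold changes correlate negatively with no effect at all. The correlation and covariance across genes are therefore given beside the mean of 100 simulations with no effect, and beside values in which no DSS library entered both comparisons. The counts of opposite changes at an unadjusted p were simulated in the same way after the results were seen. The fit was tested on simulated data built from the spread of these libraries, with 100 genes changed by a log2 fold of 1 and 100 by 2 among 14360 genes. The changed genes were drawn from those with a Control mean log2(FPKM + 1) above 2, so the shares recovered do not cover genes with lower values. For DSS against Control it recovered 65% and 97% of them, for GsMTx4 against DSS 70% and 97%, and for GsMTx4 against Control 68% and 98%. The false calls were 20 of 182, 4 of 171 and 13 of 179, and simulations with no changed gene gave 0, 1 and 0 calls.

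The alternatives were pseudocounts of 0.1 and 0.01, no filter on low values, a filter at a mean FPKM of 5, rescaling to a sum of 1e+06 per library (TPM), median-of-ratios scaling, quantile normalization, a fit of the compared groups only, sample weights, the empirical Bayes step without trend or made robust, the replicate number as a block, a minimum fold of 2, unadjusted p-values, and each library left out in turn. A correction of each library for transcript length and GC content was added after the results were seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

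Single values near 0 were read with care. Cldn2, for example, is listed at 0.00127 FPKM in Control 2 and at 42.9 and 41.0 FPKM in Control 1 and Control 3, and mt-Atp6 is at 4622 FPKM in DSS 1 and 617 FPKM in DSS 3 while its near-identical nuclear copies Gm10925 and Gm28661 vary as well. Genes that share reads with close relatives, such as the Mup and Serpina1 families, are uncertain gene by gene.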

Results

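Gene expression was measured in the colon of 8-week-old mice in 3 groups with 3 libraries each. Control mice drank normal water. DSS mice drank water with 2.5% dextran sulfate sodium (DSS), a polymer that injures the colonic epithelium and brings on colitis, for 7 days and received solvent by intravenous injection on days 2, 4 and 6. The GsMTx4 mice drank DSS in the same way and received GsMTx4 at 10 mg/kg on those days. GsMTx4 is a spider-venom peptide that inhibits cation channels opened by mechanical force, Piezo1 among them. FPKM sums ran from 349125 to 440935 per library, between 12830 and 14036 genes reached 1 FPKM, and the depth in reads is unknown. On the leading principal component, with 43.3% of the variance, the DSS libraries lay at 38.2 to 51.8, the Control libraries at -29.9 to -28.6 and the GsMTx4 libraries at -23.3 to -2.5. Below, levels are mean FPKM ± SD and log2 fold changes are ± SE, each with n = 3 libraries per group, and adjusted p-values are from limma or from its list test camera. Paragraphs on gene lists end with the counts of passing members that moved by over 1.5 times when 1 library was left out.

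The comparison of DSS with Control covers the colitis model together with the solvent injections. No injection is listed for Control mice, so effects of DSS and of injection cannot be told apart. Lrg1, which encodes a secreted glycoprotein of inflamed tissue (chromosome 17, 56119678 to 56122001, GRCm38), rose most among the genes named by rule, from 1.67 ± 0.231 to 229 ± 77.5 FPKM, a log2 fold change of 6.37 ± 0.76 (adjusted p = 0.0015). The calprotectin genes S100a8 and S100a9, abundant in neutrophils, rose by 5.37 ± 0.66 and 5.59 ± 0.89, and Cxcl5, a chemokine that attracts neutrophils (chromosome 5, 90759360 to 90761624), by 5.47 ± 0.56, from 0.275 ± 0.23 to 55.4 ± 7.29 FPKM. The chloride channel regulator Clca4b rose by 6.00 ± 0.97 and Plet1 by 5.48 ± 0.52. Of the named genes that fell, Nxpe2 (chromosome 9, 48318006 to 48353454) dropped most, from 78.4 ± 11.3 to 1.92 ± 0.818 FPKM, a log2 fold change of -4.79 ± 0.40 (adjusted p = 0.00047). Reg4, a secreted lectin of secretory epithelial cells, changed by -4.09 ± 0.59, the NADPH oxidase gene Nox1 by -3.66 ± 0.47, the cysteine dioxygenase gene Cdo1 by -3.38 ± 0.38, the glutathione transferase gene Gstm3 by -3.36 ± 0.23 and the cytochrome P450 gene Cyp2c68 by -3.25 ± 0.27.

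Most measured neutrophil markers and antimicrobial genes were higher in DSS, and members of other immune lists in part. Of 11 measured neutrophil markers 10 rose (11 adjusted over the list alone), with Ly6g going from 81.1 ± 11.9 to 691 ± 302 FPKM. Ly6g stood at 67.4 to 88.8 FPKM in the Control libraries, where S100a8 was at most 0.191 FPKM. In GsMTx4 3 Ly6g was at 544 FPKM with S100a8 at 0.893 FPKM, so Ly6g may not track neutrophils here. The neutrophil list had camera adjusted p = 2.74e-12, and adjusted p = 0.0674 with an estimated correlation. Of 14 antimicrobial and acute-phase genes 9 rose (10 higher and 1 lower adjusted over the list alone), among them the serum amyloid gene Saa3 at 3.87 ± 0.37 and Duoxa2, which matures the hydrogen peroxide source Duox2, at 2.71 ± 0.26. The antimicrobial list had camera adjusted p = 1.38e-08, and adjusted p = 0.0674 with an estimated correlation. Pro-inflammatory cytokines rose in 4 of 9 cases (7 adjusted over the list alone), with the barrier cytokine Il22 at 2.70 ± 0.43 and Il18 at 1.07 ± 0.20. The cytokine list had camera adjusted p = 8.68e-05, and adjusted p = 0.183 with an estimated correlation. Chemokines rose in 7 of 19 cases (9 adjusted over the list alone), including Cxcl1 at 2.53 ± 0.31. The chemokine list had camera adjusted p = 1.41e-05, and adjusted p = 0.181 with an estimated correlation. Among 19 genes of the NF-kB, toll-like receptor and inflammasome list 6 rose and 1 fell (11 and 2 adjusted over the list alone), with the feedback inhibitor Socs3 at 2.97 ± 0.48 and the adhesion molecule Vcam1 at 1.43 ± 0.20. The NF-kB list had camera adjusted p = 1.29e-06, and adjusted p = 0.126 with an estimated correlation. Monocyte and macrophage markers rose in 4 of 15 cases (5 adjusted over the list alone), with Chil3 at 3.50 ± 0.38 and Lyz2 at 1.39 ± 0.23. The monocyte and macrophage list had camera adjusted p = 5.08e-08, and adjusted p = 0.126 with an estimated correlation. B and plasma cell markers rose in 6 of 11 cases (10 adjusted over the list alone), with Mzb1 at 1.48 ± 0.29. The B and plasma cell list had camera adjusted p = 7.84e-07, and adjusted p = 0.191 with an estimated correlation. Falls among antimicrobial genes numbered 1 without GsMTx4 3. Rises among cytokines numbered 2 without Control 2 or Control 3 and 7 without DSS 1. Rises among chemokines numbered 4 without Control 2. Rises among NF-kB list genes numbered 3 without Control 2 or DSS 2 and 2 without Control 3. Falls among NF-kB list genes numbered 2 without DSS 2. Rises among monocyte markers numbered 2 without Control 1, Control 3 or DSS 3. Rises among B and plasma cell markers numbered 2 without Control 2, 1 without Control 3 and 3 without DSS 1 or DSS 3.

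Il1b and Tnf did not pass. Il1b stood at 4.73 FPKM in Control and 26.1 FPKM in DSS (log2 fold change 1.80 ± 0.55, adjusted p = 0.051), and Tnf at 3.72 and 10.2 FPKM (1.15 ± 0.36, adjusted p = 0.054). Il1b passed without DSS 1 (adjusted p = 0.0177) or DSS 3 (0.0337), and Tnf without DSS 1 (0.0216), GsMTx4 1 (0.0486) or GsMTx4 2 (0.0459), and both passed after median-of-ratios scaling or quantile normalization. Il6 was too low to test, at 0.0418 ± 0.051 FPKM in Control and 0.588 ± 0.66 FPKM in DSS. No T cell marker passed among 15 (0 adjusted over the list alone), nor did any of 9 MHC class II genes (0 adjusted over the list alone). As lists both were nonetheless called higher, with camera adjusted p = 0.037 for T cells and 0.0264 for MHC class II, against adjusted p = 0.59 and adjusted p = 0.506 with an estimated correlation. The T cell call was lost without Control 1 (adjusted p = 0.0973), Control 2 (0.0632) or DSS 1 (0.356, where the median was -0.02), and the MHC class II call without Control 2 (0.101) or DSS 2 (0.0758) or after quantile normalization. Rises among T cell markers numbered 1 without GsMTx4 1. Falls among T cell markers numbered 1 without GsMTx4 1 or GsMTx4 3. Rises among MHC class II genes numbered 1 without DSS 2 or DSS 3.

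Most measured epithelial repair genes were higher and most crypt stem cell genes lower. Of 11 epithelial repair genes 7 rose (9 adjusted over the list alone), including the growth factor Ereg from 1.48 to 17.8 FPKM (2.92 ± 0.24) and the urokinase receptor Plaur (2.21 ± 0.20). The repair list had camera adjusted p = 7.22e-10, and adjusted p = 0.0674 with an estimated correlation. Of 11 crypt stem cell genes 8 fell (10 adjusted over the list alone), with the Wnt target Axin2 at -1.97 ± 0.27 and the ion cotransporter Slc12a2 at -1.99 ± 0.30. The stem cell list had camera adjusted p = 1.56e-05, and adjusted p = 0.209 with an estimated correlation. The stem cell marker Lgr5 was too low to test, at 0.941 ± 0.0887 FPKM in Control and 0.0148 ± 0.0092 FPKM in DSS. Proliferation genes fell in 7 of 24 cases (23 adjusted over the list alone), among them the mitotic kinase gene Plk1 at -1.33 ± 0.25. The proliferation list had camera adjusted p = 1.99e-05, and adjusted p = 0.506 with an estimated correlation. Hypoxia and glycolysis genes rose in 6 of 14 cases (8 adjusted over the list alone), with Hif1a at 1.32 ± 0.20 and the glucose transporter Slc2a1 at 1.09 ± 0.14. The hypoxia list had camera adjusted p = 5.78e-07, and adjusted p = 0.117 with an estimated correlation. Falls among stem cell genes numbered 5 without Control 2. Falls among proliferation genes numbered 1 without Control 1 or Control 2, 4 without Control 3, 2 without DSS 2 or DSS 3 and 12 without GsMTx4 1 or GsMTx4 2.

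Other epithelial lists were not called by camera. Among 20 absorptive colonocyte genes 3 rose and 4 fell (5 and 5 adjusted over the list alone), with the carbonic anhydrase Car2 at -1.60 ± 0.22; the list's median was -0.09 and its mean -0.17 while camera pointed upward (adjusted p = 0.572). Of 15 goblet cell and mucus genes 4 fell (4 adjusted over the list alone), including the secretory lineage regulator Atoh1 at -1.53 ± 0.23 and Creb3l1 at -1.42 ± 0.22 (camera adjusted p = 0.242). Among 19 junction genes 1 rose and 2 fell (1 and 2 adjusted over the list alone), with the pore-forming claudin Cldn15 at -2.87 ± 0.33; median 0.02, mean -0.16 and an upward camera direction differed in sign (adjusted p = 0.265). Of 17 fatty acid oxidation genes 2 rose and 5 fell (3 and 7 adjusted over the list alone). Among them were the peroxisomal enzyme gene Ehhadh at -1.10 ± 0.11 and the mitochondrial regulator Ppargc1a at -1.55 ± 0.21. The fatty acid oxidation list had camera adjusted p = 0.304 and was called lower by fry (adjusted p = 0.043). Of 7 measured mechanosensitive channel genes 1 rose and 2 fell (1 and 2 adjusted over the list alone; camera adjusted p = 0.473). Piezo1 (chromosome 8, 122481698 to 122551329) did not pass, with 4.68 FPKM in Control and 6.23 FPKM in DSS (0.29 ± 0.31, adjusted p = 0.52), and Piezo2 was too low to test at 0.558 ± 0.157 and 0.469 ± 0.285 FPKM. No enteroendocrine or tuft cell marker passed among 7 (0 adjusted over the list alone; camera adjusted p = 0.152, and 0.0164 without DSS 1). Rises among colonocyte genes numbered 1 without Control 1, Control 3, DSS 1 or DSS 2. Falls among goblet cell genes numbered 2 without Control 2, Control 3 or DSS 2. Rises among junction genes numbered 0 without Control 1 or Control 3 and 2 without DSS 3 or GsMTx4 3. Falls among junction genes numbered 1 without Control 1 or Control 3. Rises among fatty acid oxidation genes numbered 1 without any 1 Control library, DSS 1 or DSS 2. Rises among mechanosensitive channel genes numbered 0 without any 1 Control library, DSS 1 or DSS 3. Falls among mechanosensitive channel genes numbered 0 without any 1 Control library, DSS 2 or DSS 3 and 1 without DSS 1. Rises among enteroendocrine and tuft cell markers numbered 1 without DSS 3.

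Many interferon-response genes were lower in DSS than in Control. Of 25 such genes 12 fell (21 adjusted over the list alone), with Oasl2 going from 87.6 to 28.4 FPKM (-1.61 ± 0.18) and Mx2 at -1.69 ± 0.19 (camera adjusted p = 4.3e-07, and adjusted p = 0.359 with an estimated correlation). Endothelial markers rose in 6 of 10 cases (8 adjusted over the list alone). The endothelial list had camera adjusted p = 7.84e-07, and adjusted p = 0.191 with an estimated correlation. In the extracellular matrix list 1 gene of 20 rose (1 adjusted over the list alone), the matrix protease gene Mmp3 at 4.31 ± 0.81. The matrix list had camera adjusted p = 6.48e-05, and adjusted p = 0.506 with an estimated correlation. The adipocyte markers Fabp4 and Cidec rose by 1.47 ± 0.19 and 1.14 ± 0.22, 2 of 4 measured (2 adjusted over the list alone). The adipocyte list had camera adjusted p = 0.00429, and adjusted p = 0.183 with an estimated correlation. Immediate early genes rose in 2 of 10 cases (3 adjusted over the list alone), with the mRNA decay factor Zfp36 at 0.68 ± 0.13 (camera adjusted p = 0.0306, and adjusted p = 0.404 with an estimated correlation); the call was lost without Control 2 or DSS 3 (adjusted p = 0.138 in each) and after median-of-ratios scaling or quantile normalization. Among enteric neuron, glia and Cajal cell markers 1 of 7 rose and 1 fell (1 and 1 adjusted over the list alone; camera adjusted p = 0.393). No member passed, over all genes or adjusted over the list alone, among 10 smooth muscle markers (camera adjusted p = 0.875), 6 distal colon position genes (0.924), 13 mitochondrially encoded mRNAs (0.209, and 0.0249 without DSS 3; median 0.07, mean -0.01) or 4 red blood cell markers (0.0585, and 0.00996 without Control 1 or 0.00107 without DSS 3). Neither of 2 measured skeletal muscle markers passed. Cela1, the only pancreatic acinar marker measured, fell by 1.36 on the log2 scale. Falls among interferon-response genes numbered 7 without Control 3. Rises among endothelial markers numbered 0 without Control 1 or Control 2, 3 without Control 3, 2 without DSS 1 and 1 without DSS 3. Rises among matrix genes numbered 4 without DSS 1 and 2 without DSS 3 or GsMTx4 3. Rises among immediate early genes numbered 1 without Control 2. Rises among enteric and Cajal cell markers numbered 0 without any 1 Control library, DSS 2 or DSS 3 and 2 without DSS 1. Falls among enteric and Cajal cell markers numbered 0 without any 1 Control library or DSS 2. Falls among skeletal muscle markers numbered 1 without DSS 3.

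In all, 921 genes rose and 1541 fell in DSS against Control among 14360 tested (adjusted p under 0.05, limma), 428 and 518 of them by at least 2-fold. The groups did not overlap for 6759 genes, 47.1% against 10% by chance. The balance of rises and falls followed the scaling: 37.4% of calls were higher as deposited, 27.5% after TPM rescaling (637 higher, 1682 lower), 60.7% after median-of-ratios scaling (1418 and 919) and 50.1% after quantile normalization (1335 and 1328), which moved the median log2 fold change of all genes by -0.106, 0.158 and 0.111, and no named gene or list that had passed turned direction under any of them. Without Control 1, Control 2 or Control 3 the counts were 492 and 786, 382 and 581, or 425 and 661, and without DSS 2 932 genes fell.

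The comparison of GsMTx4 with DSS asks what the channel inhibitor changed in colitis. Emp1, an epithelial membrane protein gene (chromosome 6, 135362545 to 135383173), fell most among the named genes, from 126 ± 49.1 to 5.44 ± 1.10 FPKM (log2 fold change -4.24 ± 0.29, adjusted p = 0.00038). Its Control level was 9.82 ± 1.89 FPKM, and the difference from Control did not pass (-0.75 ± 0.29, adjusted p = 0.433). Plet1 fell by 3.92 (SE 0.52), Cxcl5 by 3.73 (SE 0.56), S100a8 by 3.70 (SE 0.66) and Dhrs9, a retinoid dehydrogenase gene, by 3.26 (SE 0.41) on the log2 scale. Mmp3 fell by 3.38 (SE 0.81, adjusted p = 0.029), a call lost without DSS 2, DSS 3, GsMTx4 2 or GsMTx4 3 (adjusted p = 0.0758, 0.0677, 0.0992 and 0.0771). Several genes that had fallen in DSS were higher with GsMTx4, Nox1 by 3.22 ± 0.47, Nxpe2 by 3.18 ± 0.40, Cdo1 by 3.07 ± 0.38, the desaturase gene Scd2 by 2.73 ± 0.34 and Reg4 by 2.93 ± 0.59 (adjusted p = 0.016, and 0.0625 without GsMTx4 2). The largest rise among the named genes was in Alb, the liver's serum albumin gene, from 0.221 ± 0.225 to 14.1 ± 0.758 FPKM (3.64 ± 0.16, adjusted p = 4.1e-05).

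Among immune genes, several neutrophil markers and chemokines were lower with GsMTx4. Of 11 neutrophil markers 7 fell (8 adjusted over the list alone), including the interleukin-1 decoy receptor Il1r2 at -1.98 ± 0.26. The neutrophil list had camera adjusted p = 6.68e-07, and adjusted p = 0.319 with an estimated correlation. Chemokines fell in 5 of 19 cases (6 adjusted over the list alone), with the B cell attractant Cxcl13 from 170 to 27.4 FPKM (-2.47 ± 0.42) and Cxcl1 at -1.92 ± 0.31 (camera adjusted p = 0.00826, and adjusted p = 0.37 with an estimated correlation); the list call was lost without GsMTx4 2 (adjusted p = 0.0683). Antimicrobial and acute-phase genes fell in 4 of 14 cases (6 lower and 1 higher adjusted over the list alone), with the goblet cell product Retnlb at -3.11 ± 0.51, Saa3 at -2.13 ± 0.37 and the siderophore-binding Lcn2 at -1.95 ± 0.34. The antimicrobial list had camera adjusted p = 0.00269, and adjusted p = 0.319 with an estimated correlation. In the NF-kB, toll-like receptor and inflammasome list 2 of 19 fell and 1 rose (2 and 1 adjusted over the list alone), with Vcam1 at -1.59 ± 0.20, the interleukin-1 receptor Il1r1 at -1.48 ± 0.29 and the inflammasome adaptor Pycard at 0.74 ± 0.13. The NF-kB list had camera adjusted p = 0.00756, and adjusted p = 0.37 with an estimated correlation. Monocyte and macrophage markers fell in 2 of 15 cases (8 adjusted over the list alone), with Csf1r at -0.93 ± 0.18. The monocyte and macrophage list had camera adjusted p = 3.11e-05, and adjusted p = 0.319 with an estimated correlation. B and plasma cell markers fell in 2 of 11 cases (3 adjusted over the list alone). The B and plasma cell list had camera adjusted p = 0.000432, and adjusted p = 0.37 with an estimated correlation. Falls among neutrophil markers numbered 4 without any 1 Control library, DSS 2 or GsMTx4 3 and 3 without GsMTx4 2. Rises among antimicrobial genes numbered 1 without GsMTx4 3. Rises among NF-kB list genes numbered 2 without DSS 2. Falls among monocyte markers numbered 1 without Control 3, DSS 2, DSS 3 or GsMTx4 2 and 4 without DSS 1. Falls among B and plasma cell markers numbered 1 without Control 1, DSS 1, DSS 3, GsMTx4 1 or GsMTx4 3 and 0 without GsMTx4 2.

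Of the pro-inflammatory cytokines, which the series title concerns, 1 of 9 passed (2 adjusted over the list alone). Il33, an alarmin of stromal and epithelial cells, fell by 1.65 (SE 0.45, adjusted p = 0.045) on the log2 scale, and its adjusted p lay between 0.0547 and 0.116 when any 1 library other than DSS 1 was left out. The list was called lower (camera adjusted p = 0.0452, and adjusted p = 0.377 with an estimated correlation), and not without DSS 2 (adjusted p = 0.168), DSS 3 (0.0919) or GsMTx4 2 (0.128), nor after median-of-ratios scaling or quantile normalization. Il1b stood at 26.1 FPKM in DSS and 10.2 FPKM with GsMTx4 (-0.84 ± 0.55, adjusted p = 0.34), Tnf at 10.2 and 7.88 FPKM (-0.30 ± 0.36, adjusted p = 0.61) and Il22 at 6.02 and 1.86 FPKM (-1.50 ± 0.43, adjusted p = 0.051, and 0.0293 without GsMTx4 2; it also passed after median-of-ratios scaling or quantile normalization). Il6 was untested at 0.0618 ± 0.0548 FPKM with GsMTx4. No T cell marker passed among 15 and no MHC class II gene among 9 (0 adjusted over the list alone in each), while both lists were called lower, with camera adjusted p = 0.00161 and 0.0088, against adjusted p = 0.377 in each with an estimated correlation; the MHC class II call was lost without GsMTx4 2 (adjusted p = 0.0961). Rises among T cell markers numbered 1 without GsMTx4 1. Falls among T cell markers numbered 2 without DSS 2. Falls among MHC class II genes numbered 3 without GsMTx4 3.

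Some epithelial repair genes were lower and some crypt stem cell genes higher with GsMTx4. Of 11 repair genes 5 fell (7 adjusted over the list alone), among them the growth factors Ereg at -2.76 ± 0.24, Areg at -1.58 ± 0.22 and Hbegf at -1.37 ± 0.24, and Plaur at -1.70 ± 0.20. The repair list had camera adjusted p = 1.26e-06, and adjusted p = 0.286 with an estimated correlation. Of 11 stem cell genes 4 rose (9 adjusted over the list alone), with Slc12a2 at 1.46 ± 0.30 (adjusted p = 0.0547 without DSS 3) and Axin2 from 0.69 to 3.17 FPKM (1.24 ± 0.27; adjusted p = 0.0569, 0.0646 and 0.0543 without DSS 2, GsMTx4 2 or GsMTx4 3). The stem cell list had camera adjusted p = 0.00035, and adjusted p = 0.37 with an estimated correlation. In the proliferation list 1 of 24 rose (0 adjusted over the list alone). The proliferation list had camera adjusted p = 0.00101, and adjusted p = 0.464 with an estimated correlation. Absorptive colonocyte genes rose in 5 and fell in 5 of 20 cases (7 and 7 adjusted over the list alone), with Car2 at 1.71 ± 0.22 and the water channel Aqp8 at 1.68 ± 0.32 (camera adjusted p = 0.293). Of 15 goblet cell genes 1 rose and 1 fell (1 and 1 adjusted over the list alone; camera adjusted p = 0.476, and 0.0436 without DSS 1). Of 19 junction genes 2 rose and 1 fell (2 and 1 adjusted over the list alone), with Cldn15 at 2.07 ± 0.33; median -0.17, mean 0.15 and a downward camera direction differed in sign (adjusted p = 0.293). Of 17 fatty acid oxidation genes 4 rose and 2 fell (6 and 5 adjusted over the list alone), with Ehhadh at 1.13 ± 0.11 and Angptl4, an inhibitor of lipoprotein lipase, at -1.86 ± 0.27; median 0.27 and upward camera direction stood against a mean of -0.07 (adjusted p = 0.68). Rises among stem cell genes numbered 2 without any 1 Control library or DSS 3 and 1 without DSS 2, GsMTx4 2 or GsMTx4 3. Rises among proliferation genes numbered 0 without any 1 Control library, any 1 DSS library, GsMTx4 2 or GsMTx4 3 and 4 without GsMTx4 1. Rises among colonocyte genes numbered 3 without any 1 Control library, DSS 3 or GsMTx4 3 and 2 without DSS 2 or GsMTx4 2. Falls among colonocyte genes numbered 2 without Control 2, DSS 1 or GsMTx4 2, 3 without Control 3 or GsMTx4 3 and 1 without DSS 2. Rises among goblet cell genes numbered 0 without any 1 Control library, any 1 DSS library, GsMTx4 1 or GsMTx4 2. Falls among goblet cell genes numbered 0 without Control 2, DSS 2 or DSS 3. Rises among junction genes numbered 1 without DSS 3. Falls among junction genes numbered 0 without DSS 1, DSS 2, GsMTx4 2 or GsMTx4 3. Falls among fatty acid oxidation genes numbered 1 without Control 2, Control 3, DSS 1, DSS 2, GsMTx4 2 or GsMTx4 3.

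Hypoxia and glycolysis genes fell in 2 of 14 cases (2 adjusted over the list alone), with Slc2a1 at -0.85 ± 0.14 (camera adjusted p = 0.00161, and adjusted p = 0.319 with an estimated correlation; 0.0696 without DSS 2). Extracellular matrix genes fell in 5 of 20 cases (12 adjusted over the list alone), with the gelatinase gene Mmp2 at -1.22 ± 0.23. The matrix list had camera adjusted p = 6.68e-07, and adjusted p = 0.37 with an estimated correlation. Endothelial markers fell in 2 of 10 cases (7 adjusted over the list alone). The endothelial list had camera adjusted p = 4.54e-05, and adjusted p = 0.37 with an estimated correlation. The adipocyte markers Cidec and Fabp4 fell by 1.54 (SE 0.22) and 1.31 (SE 0.19), 2 of 4 measured (2 adjusted over the list alone). The adipocyte list had camera adjusted p = 0.00756, and adjusted p = 0.319 with an estimated correlation. Immediate early genes fell in 3 of 10 cases (4 adjusted over the list alone). The immediate early list had camera adjusted p = 0.00158, and adjusted p = 0.319 with an estimated correlation. Red blood cell markers fell in 1 of 4 cases (4 adjusted over the list alone; camera adjusted p = 0.00877, and adjusted p = 0.37 with an estimated correlation; 0.0681 without DSS 2), and enteroendocrine and tuft cell markers in 1 of 7 (2 adjusted over the list alone; camera adjusted p = 0.0335, and adjusted p = 0.37 with an estimated correlation; 0.113, 0.103 and 0.0555 without DSS 2, DSS 3 or GsMTx4 1, and lost after median-of-ratios scaling or quantile normalization). Of 25 interferon-response genes 1 rose (0 adjusted over the list alone), with a list median of 0.66. The interferon list had camera adjusted p = 0.000245, and adjusted p = 0.378 with an estimated correlation. Of 7 mechanosensitive channel genes 1 rose and 1 fell (2 and 1 adjusted over the list alone; camera adjusted p = 0.424), and Piezo1 did not pass, at 6.23 FPKM in DSS and 4.05 FPKM with GsMTx4 (-0.52 ± 0.31, adjusted p = 0.29); Piezo2 was untested at 0.439 ± 0.0906 FPKM with GsMTx4. Rises among hypoxia genes numbered 1 without DSS 2. Falls among hypoxia genes numbered 1 without DSS 1, DSS 3 or GsMTx4 2. Falls among matrix genes numbered 3 without any 1 Control library, 2 without DSS 2, 1 without DSS 3, GsMTx4 2 or GsMTx4 3 and 8 without GsMTx4 1. Falls among endothelial markers numbered 1 without any 1 Control library, 4 without DSS 2 and 0 without DSS 3, GsMTx4 2 or GsMTx4 3. Falls among immediate early genes numbered 0 without GsMTx4 2. Falls among red blood cell markers numbered 0 without Control 2, Control 3, DSS 1, DSS 2, GsMTx4 2 or GsMTx4 3 and 4 without DSS 3. Falls among enteroendocrine and tuft cell markers numbered 0 without any 1 Control library, DSS 2, GsMTx4 2 or GsMTx4 3. Rises among interferon-response genes numbered 0 without Control 1, Control 3, DSS 1, GsMTx4 2 or GsMTx4 3, 4 without DSS 3 and 2 without GsMTx4 1. Rises among mechanosensitive channel genes numbered 0 without any 1 Control library, any 1 DSS library, GsMTx4 1 or GsMTx4 2 and 2 without GsMTx4 3. Falls among mechanosensitive channel genes numbered 0 without any 1 Control library, any 1 DSS library, GsMTx4 2 or GsMTx4 3.

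Some markers of tissue position and RNA makeup differed as well. CT010467.1, annotated as a ribosomal RNA gene and singled out after its values were seen, changed by -1.61 ± 0.35 against DSS (adjusted p = 0.0201, limma). Mitochondrial genes held 14.5% to 18.05% of all FPKM in the GsMTx4 libraries, 9.12% to 13.65% in DSS and 10.6% to 14.21% in Control. None of 13 mitochondrially encoded mRNAs passed (0 adjusted over the list alone), and the list was called higher with GsMTx4 (camera adjusted p = 0.0119, and adjusted p = 0.464 with an estimated correlation; 0.103 without DSS 3 and 0.143 without GsMTx4 3). Distal colon position genes, homeobox genes that mark the lower colon, rose in 1 of 6 cases (2 adjusted over the list alone; camera adjusted p = 0.0384, and adjusted p = 0.377 with an estimated correlation), and the call was lost without DSS 3 (adjusted p = 0.146), GsMTx4 1 (0.13) or GsMTx4 3 (0.166). No smooth muscle marker passed among 10 (0 adjusted over the list alone; camera adjusted p = 0.5, and 0.0343 without DSS 3). Among 7 enteric neuron, glia and Cajal cell markers 1 rose and 1 fell (1 and 1 adjusted over the list alone; camera adjusted p = 0.504). Neither of 2 skeletal muscle markers passed. Cela1, the only acinar marker measured, rose by 1.83 ± 0.23. It stood at 57.5 to 64.3 FPKM in Control, 20.9 to 25.4 FPKM in DSS and 64.9 to 126 FPKM with GsMTx4. As Cela1 was also high in Control, its rise is no sign of pancreatic tissue. Of the genes higher with GsMTx4, 27 are hepatocyte genes, and Alb stood at 13.2, 14.4 and 14.6 FPKM in the 3 GsMTx4 libraries. Of these 27 genes, 22 had been picked from the top of the ranking in these same libraries, so their number is no test. In a list of hepatocyte genes not looked at before, 5 of 11 tested genes rose and 1 fell. Rises among distal colon genes numbered 0 without any 1 library. Rises among enteric and Cajal cell markers numbered 0 without any 1 Control library, DSS 2, DSS 3 or any 1 GsMTx4 library. Falls among enteric and Cajal cell markers numbered 0 without Control 2, Control 3, DSS 2, DSS 3, GsMTx4 2 or GsMTx4 3 and 2 without DSS 1. Rises among skeletal muscle markers numbered 1 without DSS 3.

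In all, 956 genes rose and 807 fell in GsMTx4 against DSS (adjusted p under 0.05, limma), 312 and 333 of them by at least 2-fold, and 4349 genes did not overlap between the groups, 30.3% against 10% by chance. As deposited 54.2% of the calls were higher, and 43.3% after median-of-ratios scaling (818 higher, 1069 lower). Without GsMTx4 2 the counts were 393 and 323, and without Control 2, Control 3 or DSS 3 they were 589 and 500, 621 and 516, or 551 and 461, while without DSS 1 or DSS 2 632 or 606 genes rose. A fit without the Control libraries, which varied less within their group than the others did, called 327 and 260.

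**Figure D1:**
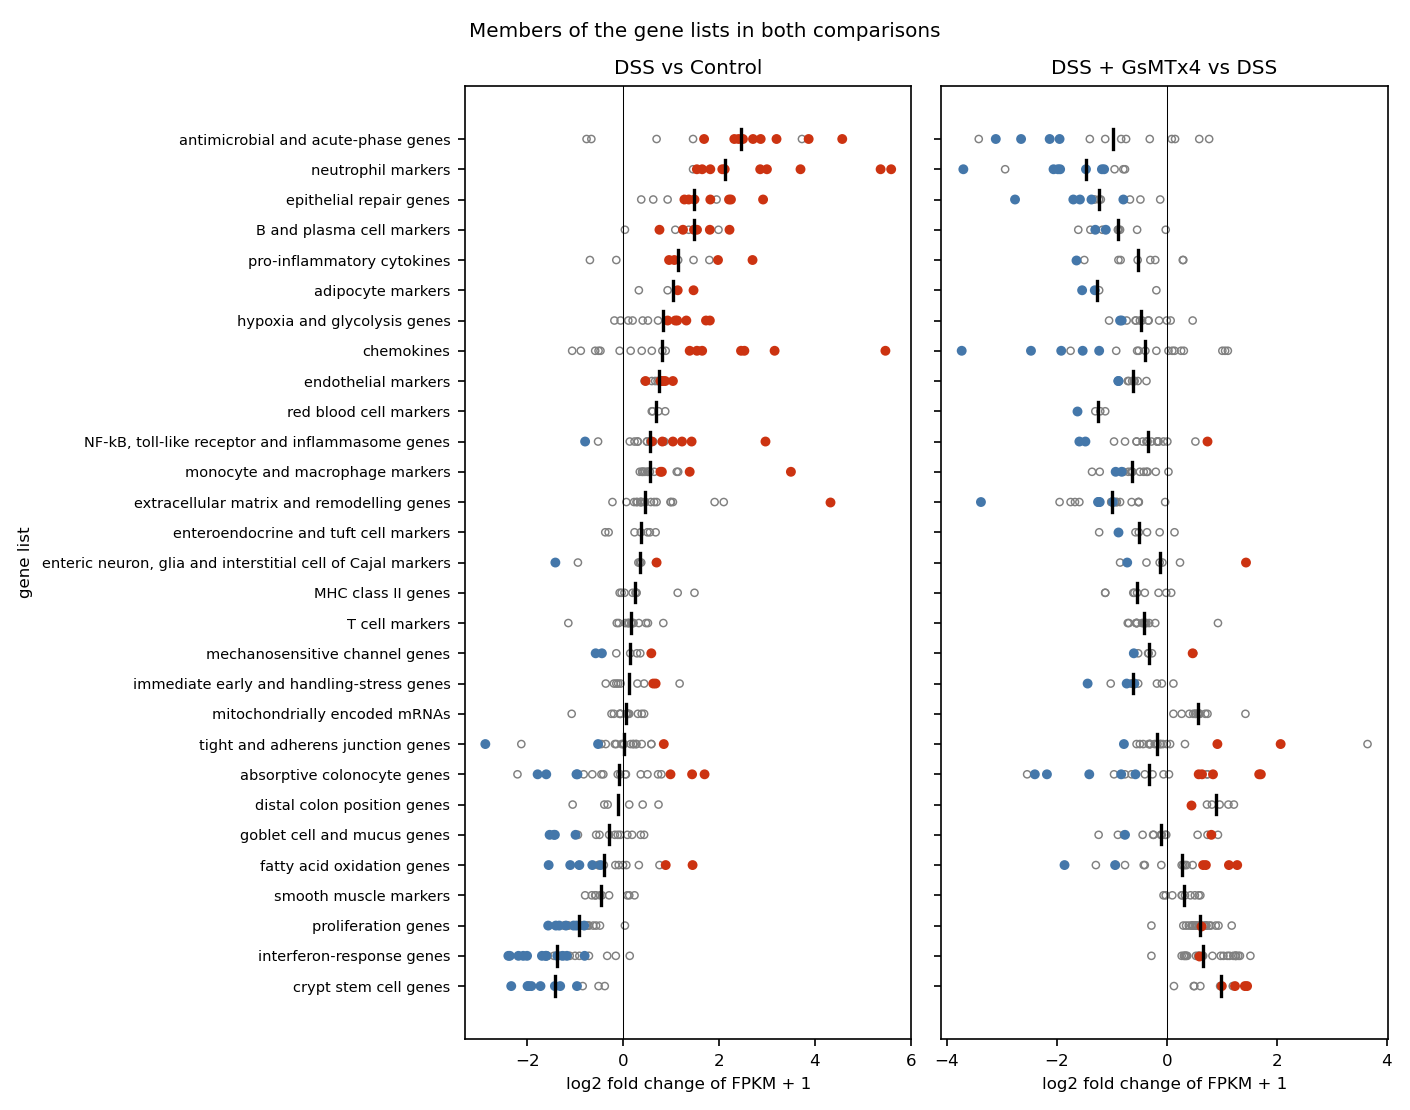
Log2 fold changes of the tested members of each gene list in DSS against Control and in GsMTx4 against DSS; filled red and blue points passed as higher or lower at an adjusted p under 0.05, open grey points did not pass, and black ticks mark list medians. Neutrophil markers have a median of 2.12 in DSS against Control and -1.47 in GsMTx4 against DSS, and crypt stem cell genes -1.42 and 0.99.

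Setting both comparisons side by side shows where genes that changed in DSS stood under GsMTx4. Among genes that rose in DSS, 536 fell with GsMTx4, and among genes that fell in DSS, 724 rose with GsMTx4. Independent lists of these sizes would give 51.8 and 102.6. At an unadjusted p under 0.05 in both comparisons 3149 genes changed in opposite directions and 5 in the same direction, against means of 165.3 and 2.5 in 100 simulations with no effect and the same shared DSS libraries. The simulations leave out real effects and the independent lists leave out the shared libraries, so part of the excess over either may come from the shared libraries. The simulations also gave all libraries of a gene the same spread. The DSS libraries varied more (mean absolute deviation 0.1994 to 0.2316) than the Control libraries (0.1156 to 0.154). The simulated counts, and the simulated correlation and covariance below, may therefore understate what shared libraries alone give. Ranked by the fold change in GsMTx4 against DSS alone, Emp1, Plet1, Cxcl5, S100a8 and Mmp3 changed most among named genes that rose in DSS. By the same ranking Alb changed most among those that fell. Alb had fallen by only 0.67 in DSS. At 14.1 FPKM with GsMTx4 it lay far above its Control level of 0.933 FPKM, so it did not return to that level. The single gene higher in both comparisons was Hamp, the iron hormone hepcidin, picked out here after its values were seen, and 0 genes were lower in both. Hamp and Alb are among the hepatocyte genes that were higher in the GsMTx4 libraries, so RNA or reads from liver may lie behind their rise with GsMTx4. Across genes, which are not independent replicates, the fold changes correlated at r = -0.831, against -0.499 simulated with no effect and the same shared DSS libraries; the covariance was -0.296 against -0.033, a difference of -0.263. With no DSS library in both comparisons r was -0.647 to -0.559 and the covariance -0.261 to -0.23. Without Control 1, Control 2, Control 3, DSS 3 or GsMTx4 2 the counts of opposite changes were 298 and 434, 251 and 352, 265 and 384, 324 and 455, or 249 and 334, and without DSS 2 423 genes fell in DSS and rose with GsMTx4. Of the 1763 genes that passed in GsMTx4 against DSS, 502 had not passed in DSS against Control.

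**Figure D2:**
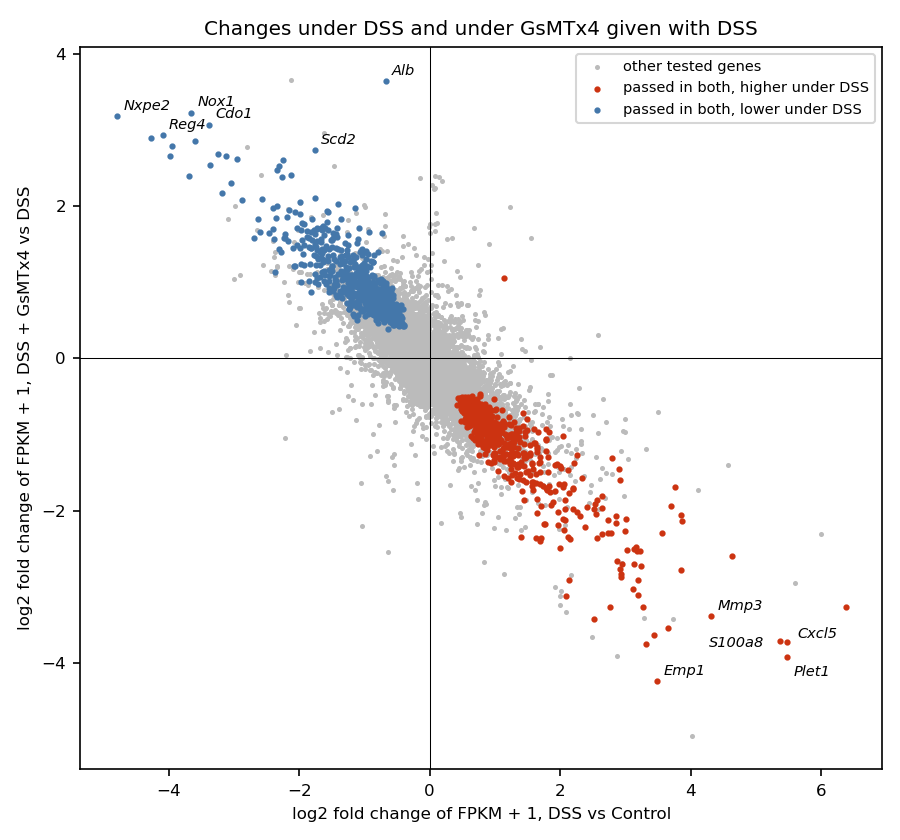
Log2 fold change in DSS against Control (horizontal) and in GsMTx4 against DSS (vertical) for each of 14360 tested genes; red points passed in both comparisons and were higher in DSS, blue points passed in both and were lower in DSS, and grey points did not pass in both. Of the red points 536 lie below 0 on the vertical axis and 1, the hepatocyte gene Hamp, above it, and all 724 blue points lie above it.

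The comparison of GsMTx4 with Control sets the GsMTx4 mice against mice on normal water, for which no injection is listed. Of the 34 genes that passed, 10 had also passed in DSS against Control. Alb was highest in fold among the named genes, at 14.1 ± 0.758 FPKM against 0.933 ± 0.252 in Control (2.97 ± 0.16, adjusted p = 0.00025; chromosome 5, 90460897 to 90476602). The heme-binding plasma protein gene Hpx rose by 2.53 ± 0.36 (adjusted p = 0.031) and Chil3, a chitinase-like gene of myeloid cells, by 2.80 ± 0.38 (adjusted p = 0.026). Of the 27 genes that rose, 21 are hepatocyte genes, and Ly6g, Duoxa2 and the clock output gene Dbp, singled out after their values were seen, are among the rest. All 21 had been picked from these same libraries, and 0 of 11 tested hepatocyte genes not looked at before passed. Nek7, a kinase that takes part in NLRP3 inflammasome assembly (chromosome 1, 138482875 to 138620141), fell from 10.2 ± 0.236 to 2.84 ± 0.267 FPKM (-1.54 ± 0.15, adjusted p = 0.0036) and was already at 3.93 ± 1.02 FPKM in DSS. CT010467.1, annotated as a ribosomal RNA gene on chromosome 17, fell by 2.26 (SE 0.35, adjusted p = 0.045) and Pdzd7 by 1.24 (SE 0.19, adjusted p = 0.048). Il1b and Tnf did not pass, at 0.97 ± 0.55 (adjusted p = 0.58) and 0.85 ± 0.36 (0.47), nor did Piezo1, at -0.23 ± 0.31 (0.83).

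Across the gene lists few members passed in GsMTx4 against Control, while 11 lists were called higher and 5 lower by camera and 0 with an estimated correlation or by fry. Antimicrobial and acute-phase genes rose in 1 of 14 cases (6 adjusted over the list alone), with a median of 1.24 (camera adjusted p = 6.5e-09, and adjusted p = 0.163 with an estimated correlation), and neutrophil markers in 1 of 11 (1 adjusted over the list alone; camera adjusted p = 7.19e-09, and adjusted p = 0.211 with an estimated correlation). That neutrophil marker was Ly6g, which may not track neutrophils here. Mitochondrially encoded mRNAs rose in 0 of 13 cases (3 adjusted over the list alone; camera adjusted p = 1.02e-08, and adjusted p = 0.242 with an estimated correlation). Cytokines, chemokines and NF-kB genes had 0 passing members (1 each adjusted over the list alone; camera adjusted p = 5.24e-05, 0.000181 and 0.000181, and adjusted p = 0.235, 0.242 and 0.242 with an estimated correlation). Hypoxia, repair, B and plasma cell and distal colon genes had 0 passing members by either adjustment (camera adjusted p = 2.02e-05, 0.000577, 0.00253 and 0.00199, and adjusted p = 0.235, 0.235, 0.525 and 0.34 with an estimated correlation). Monocyte and macrophage markers rose in 1 of 15 cases (1 adjusted over the list alone), with a median of -0.04 against a mean of 0.23 and an upward camera call (adjusted p = 0.0244, and adjusted p = 0.525 with an estimated correlation). Lower lists were interferon-response genes (0 of 25, 7 adjusted over the list alone), goblet cell, crypt stem cell, proliferation and extracellular matrix genes (0 by either adjustment), with camera adjusted p = 5.24e-05, 0.000181, 0.0109, 0.0212 and 0.037, and adjusted p = 0.525, 0.395, 0.525, 0.685 and 0.685 with an estimated correlation. The other tested lists had 0 passing members by either adjustment and camera adjusted p from 0.0933 to 0.941; junction, smooth muscle and adipocyte genes had medians of -0.05, -0.06 and -0.08 and enteric genes a mean of -0.05 with an upward camera direction.

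List calls in this comparison moved with single libraries. Without GsMTx4 1 the calls for repair (adjusted p = 0.112), stem cell (0.114), proliferation (0.972) and monocyte genes (0.15) were lost, and without GsMTx4 3 those for distal colon (0.0635), B and plasma cell (0.128), matrix (0.326) and monocyte genes (0.251), while MHC class II (0.0159) and T cell lists (0.00901) were called lower. Without GsMTx4 2 the matrix call was lost (0.215) and the endothelial list called higher (0.0315). Without Control 1 the matrix (0.0669), proliferation (0.384) and monocyte calls (0.0922) were lost and fatty acid oxidation genes called lower (0.00262), and without Control 2 red blood cell (0.0224) and immediate early genes (0.0171) were called lower. Without Control 3 the monocyte (0.0929) and B and plasma cell calls (0.0651) were lost and the endothelial list called higher (0.0119), and without DSS 2 the matrix call was lost (0.0615). Rises among cytokines numbered 2 without GsMTx4 3. Rises among chemokines numbered 1 without Control 1 or GsMTx4 3. Rises among NF-kB list genes numbered 1 without GsMTx4 3. Rises among antimicrobial genes numbered 0 without Control 2, Control 3, DSS 2 or GsMTx4 2, 2 without DSS 3 and 3 without GsMTx4 3. Rises among hypoxia genes numbered 1 without GsMTx4 3. Rises among neutrophil markers numbered 0 without any 1 Control library, DSS 1 or any 1 GsMTx4 library. Rises among monocyte markers numbered 0 without Control 2, Control 3, DSS 2, GsMTx4 1 or GsMTx4 2. Falls among interferon-response genes numbered 1 without DSS 2 and 2 without DSS 3. Falls among fatty acid oxidation genes numbered 1 without Control 1.

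In all, 27 genes rose and 7 fell in GsMTx4 against Control (adjusted p under 0.05, limma), 27 and 6 by at least 2-fold, with 401 and 1055 at an unadjusted p under 0.05. The groups did not overlap for 2817 genes, 19.6% against 10% by chance. The count of rises was 13, 12, 17, 17 and 70 without Control 2, Control 3, DSS 2, GsMTx4 1 or GsMTx4 3, and that of falls 4, 2, 1, 4, 2, 2 and 13 without Control 1, Control 2, Control 3, DSS 1, GsMTx4 1, GsMTx4 2 or GsMTx4 3. Nek7 passed under each setting tried where it was tested, and Alb under each such setting but the pseudocount of 0.01 (adjusted p = 0.101). Hpx and Pdzd7 were lost without any 1 Control library, any 1 DSS library or GsMTx4 2 (adjusted p = 0.055 to 0.15 and 0.0737 to 0.246), and Pdzd7 also without GsMTx4 1 (0.0888). Chil3 was lost without Control 2, Control 3, DSS 2, GsMTx4 1 or GsMTx4 2 (adjusted p = 0.0578 to 0.15), and CT010467.1 without any 1 Control library, DSS 1, DSS 2, GsMTx4 1 or GsMTx4 2 (0.062 to 0.22). CT010467.1 and Pdzd7 were each also lost under 2 of the scalings. Under the remaining settings that changed the fit Hpx, Chil3, CT010467.1 and Pdzd7 were lost 3, 4, 5 and 6 times.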

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

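The correction for transcript length and GC content was chosen after the results were seen. No named gene that had passed turned direction under any setting, nor did the camera or fry direction of a called list. List medians near 0 did change sign: the T cell median in DSS against Control went from 0.171 to -0.017 without DSS 1, the immediate early median from 0.127 to -0.001 without Control 2, and the monocyte median in GsMTx4 against Control from -0.044 to above 0 under 6 settings. Of the named genes that passed in DSS against Control, GsMTx4 against DSS and GsMTx4 against Control, 44 of 62, 32 of 70 and 1 of 6 passed under every setting that tested them, a minimum fold aside, and of the lists 15 of 18, 14 of 22 and 9 of 16 kept their camera call under the settings that changed the fit. Depth in reads is unknown, so no value here can be tied to it. Counts below are higher and lower for DSS against Control, then GsMTx4 against DSS, then GsMTx4 against Control. A minimum fold of 2 gave 428 and 518, 312 and 333, with 218 and 224 opposite changes, and an unadjusted p gave 1683 and 3331, 2463 and 1861, 401 and 1055, as these thresholds must. With an estimated correlation camera called 0 lists in each direction of each comparison, since it allows for members that vary together, and fry called 1 higher and 8 lower in GsMTx4 against DSS and 0 and 0 in GsMTx4 against Control. Pseudocounts of 0.1 and 0.01 gave 2 and 1 lower, and the latter 3 higher, in GsMTx4 against Control. Without a filter GsMTx4 against DSS gave 590 and 483, GsMTx4 against Control 12 lower, opposite changes 325 and 411, and 5 lists were called lower in DSS against Control. A mean FPKM of 5, which tests fewer genes, gave 579 and 992, 495 lower, 3 and 2, with 327 opposite changes from higher to lower and 3 lists lower in GsMTx4 against Control. TPM gave 347 opposite changes from higher to lower; median-of-ratios scaling gave 1418 and 919 in DSS against Control, 3 lower in GsMTx4 against Control and 822 opposite changes from higher to lower; quantile normalization gave 3 lower in GsMTx4 against Control. Fitting 2 groups only gave 985 and 1956 in DSS against Control, 327 and 260 in GsMTx4 against DSS and 208 and 277 opposite changes. The calls in DSS against Control did not drop, but that fit also lost the GsMTx4 libraries, which varied more than the Control libraries. It therefore cannot tell how far fewer residual degrees of freedom explain the drop in GsMTx4 against DSS. Mean absolute deviations from the group mean were 0.1156 to 0.154 in Control, 0.1994 to 0.2316 in DSS and 0.1926 to 0.2632 in GsMTx4 libraries. The joint fit pools the tighter Control libraries into the spread used for GsMTx4 against DSS. Sample weights gave 1524 and 2750, 98 and 84 in GsMTx4 against Control, 3 lists higher in GsMTx4 against DSS and 3 lower in GsMTx4 against Control. With 1 DSS library in the drug comparison and the others in DSS against Control, r was -0.572, -0.647 and -0.559. The covariance was -0.23, -0.261 and -0.249, against -0.296 with all libraries. These splits share no library but also put fewer DSS libraries in each comparison, so the change in r cannot be put down to sharing alone. Leaving out each library in turn gave 382 to 1094 and 581 to 2007, 393 to 1209 and 323 to 787, 12 to 70 and 1 to 13, with 249 to 519 and 334 to 864 opposite changes, 3 to 5 lists higher in GsMTx4 against DSS and 3 to 7 lower in GsMTx4 against Control. Except where a reason is given, the cause was not tested.

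The replicate numbers are shared between groups. Over 9 pairs with the same number the deviations from the group means correlated at -0.233 to 0.1, with 0 over 0.1, and the best partner had the same number in 2 of 9 cases. The highest correlation between groups was 0.311, for DSS 2 with GsMTx4 3. These values gave no sign of pairing by number, but so few libraries cannot exclude a shared day, litter or batch. The replicate block gave 995 lower in DSS against Control, 553 and 525 in GsMTx4 against DSS, and 424 genes that fell in DSS and rose with GsMTx4.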

Other observations

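The lists in this opening paragraph, the counts of hepatocyte and clock genes that passed against Control, and the tests of a single liver source, of the shared DSS libraries and of other splits of the libraries, were chosen after the results were seen. Genes of glutathione and xenobiotic metabolism were lower in DSS in 9 of 17 measured cases and higher in 1, and with GsMTx4 they were higher than in DSS in 8 and lower in 1. The glutathione transferases Gstm1 and Gsta3 changed by -2.40 ± 0.20 and -2.26 ± 0.20 in DSS and by 1.69 ± 0.20 and 2.38 ± 0.20 with GsMTx4 (log2 fold change ± SE, n = 3). Of 19 lipid and sterol synthesis genes 4 fell in DSS, and 8 rose and 1 fell with GsMTx4; Acss2, which makes acetyl-CoA from acetate, changed by -1.99 ± 0.15 and 1.90 ± 0.15, and the desaturase gene Fads2 by -1.62 ± 0.14 and 1.62 ± 0.14. Immunoglobulin constant genes of plasma cells rose in DSS in 6 of 9 cases and fell with GsMTx4 in 4, with Ighg2c at 113, 1148 and 181 FPKM in Control, DSS and GsMTx4. Of 7 cornified envelope and squamous genes 5 rose in DSS and 3 fell with GsMTx4, among them the serine protease gene Prss27 at 3.13 ± 0.27 and -2.69 ± 0.27. Of 4 fucosylation and glycolipid genes 1 rose in DSS, Fut2 at 2.09 ± 0.50, and 0 passed with GsMTx4. None of 4 Y-linked genes passed in any comparison by limma, and all 9 libraries had Y-linked genes above 1 FPKM and Xist below 1 FPKM.

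Transcripts typical of hepatocytes were present in each GsMTx4 library, with Apoa1 at 4.15, 4.68 and 3.57 FPKM and at most 0.122 FPKM elsewhere, and Alb at 14.1 ± 0.758 FPKM. Of 30 hepatocyte genes not looked at before, 29 were detected and 55.2% (16) were higher in each GsMTx4 library than in the other 6 libraries, against 1.2% by chance per gene, so RNA or reads from liver may have entered these libraries; 22 of the 52 listed genes had been picked from these same libraries and the colon expresses 8 at 1 FPKM or more. The 1.2% assumes no difference between groups, and the same share over all genes was not computed. Among all tested genes 30.3% did not overlap, in either direction, between GsMTx4 and DSS and 19.6% between GsMTx4 and Control. Of the 16 genes that were higher in each GsMTx4 library 14 lay below the filter. Of the 11 of the 30 genes that were tested, 5 rose and 1 fell against DSS by limma, and 0 passed against Control, with 5 higher and 0 lower at an unadjusted p under 0.05. Expression of acute-phase genes by the colon itself cannot be told apart from this: 58.3% of the metabolic enzymes (7 of 12, SE 14.2%) were higher in each GsMTx4 library, above the bound of 50% set beforehand, but that bound lies within 1 SE, a margin asked for with the value known, and all 7 lay below the filter. The balance of acute-phase to Mup genes ranged over 3.4 log2 units between the 3 libraries (-1.23, -1.51 and 1.89), a spread that rests on GsMTx4 3 and was set against a bound chosen with the value known, so whether there was 1 common source cannot be told apart. Liver transcripts coincide with the treatment group, and the labels do not say how tissue was taken or in what order.

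Clock genes differed from DSS as well, with Dbp at 16, 13.2 and 20.9 FPKM in the GsMTx4 libraries and 1.68 to 3.62 FPKM elsewhere. The other genes driven by the clock (the output genes, with the Per and Nr1d genes among them) had a median log2 change of 0.95 against DSS. Of the 9 tested output genes, Dbp included, 5 were higher than in DSS and 0 lower by limma. Per1 was at -0.40 (adjusted p = 0.374, limma), and Per2, Nr1d1 and Tef did not pass. A list of 5 genes expected to move against them had -0.86; it held the activator genes Arntl (-0.95), Npas2 (-0.84) and Clock (1.05) and the repressor genes Cry1 (-0.86) and Nfil3 (-1.36). Another clock phase in the GsMTx4 mice could give such opposite medians, although Clock and, short of passing, Per1 went against the median of their lists. A return of DSS-changed genes to the Control level is argued against only by a narrow margin. The median of the 11 listed output genes lay 0.73 above Control (bound 0.5). It was 0.67 without Dbp, whose value had been seen beforehand, and 0.81 over the 9 tested genes. The bootstrap SE of 0.18 resampled genes of the same libraries, so it leaves out the spread between libraries. Without Dbp the bound lies within 1 such SE. In DSS the output genes had a median of -0.03 against Control, with 2 of 9 tested genes lower, so as a set they had little fall to return from. Clock itself changed by -1.16 in DSS and stood at -0.11 against Control with GsMTx4. Against Control 1 of 9 tested output genes, Dbp, passed by limma, 7 were higher at an unadjusted p under 0.05, and 8 lay above Control in each library. Of the 5 genes expected to move against them 0 passed by limma and 3 were lower at an unadjusted p under 0.05. The time of day at collection is not in the labels, and an effect of the drug on the clock was not tested.

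The opposite movement of DSS-changed genes under GsMTx4 was weighed against 2 technical explanations. With no DSS library in both comparisons the covariance of the fold changes stayed at -0.23 or below, where shared libraries alone would bring it near 0. After correction for transcript length and GC content the number of genes with opposite changes was 132.9% of that before, which argues against such a bias as the cause. An effect of GsMTx4 on colitis stays open as a hypothesis, as do a lower intake of DSS or a milder course in that group for other reasons, which could not be tested because intake, weight and histology were not analysed here.

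The 6 libraries of a comparison allow 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 2462, 1763 and 34 genes in DSS against Control, GsMTx4 against DSS and GsMTx4 against Control, and the highest other split 1 gene in each, so that 1 split of 10 reached the real value.

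DSS 3 was highest of the 9 libraries for Timp1 (60.3 FPKM), Mmp3 (91.6 FPKM) and S100a9 (172 FPKM). GsMTx4 3 had the largest share of FPKM in its top 10 genes (22.64%), the lowest mean correlation with its group (0.9436) and a value of -44.7 on the principal component with 16.5% of the variance.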
